A study of Homo sapiens with 38 samples.

How the data were processed

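Total RNA of T-HESC cells was sequenced after ribosomal RNA depletion, stranded and single-end with 50 bp reads, per the labels' protocols. Cells were transfected for 6 hours with 50 nM siRNA and collected after 48 hours, and the protocol states a knockdown of over 70%, per the labels' protocols. The 38 samples were 8 control samples and 6 samples per knockdown, each library having been run 2 times. The 4 control cultures were used 3 per comparison, per the labels' descriptions, so that RXRA and RORB knockdown shared all 3 controls, PHB and MLLT11 knockdown did too, and every other pair shared 2. For control culture 3 the descriptions of its 2 runs conflict, 1 repeating that of culture 2, and the other was used. Control levels were within 0.01 on the log2 scale for 75.1% and 76.3% of transcripts in the pairs taken to share 3 controls, and for at most 8.70% in other pairs. Which culture was left out of a comparison still rests on the descriptions.

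Reads were aligned with HISAT2 2.1.0 and handled with StringTie 1.3.6 and DESeq2 2.11.40.6 by the authors, with edgeR and limma also named, on genome build hg38, per the submitters' processing notes. Which tool made the counts, the annotation release and any filter are not stated there. The deposited tables give 1 line per Ensembl transcript, and these were used here in place of genes and of counts per library, for which the design fixed beforehand had an alternative. The base mean is a signal in normalised counts, averaged by the authors over the libraries of a comparison, per the file headers. The log2 fold change and its standard error are values the authors deposited, per the file headers, and every error after ± is that standard error. The Wald statistic is a score the authors deposited, equal on recomputation to the log2 fold change over its standard error. Each p-value and adjusted p-value of a transcript is the authors' DESeq2 Wald test, two-sided, as deposited. The 6 most frequent single-count levels among low base means were read per table, and 3 were of the knockdown and 3 of the control group. The number 6 was set in that reading, so it cannot by itself show that the 2 runs of a library were merged. The size factors read from these levels, taking 6 libraries, lay between 0.973 and 1.11. Values near 1 go with runs that had not entered as separate replicates. The tables listed 100454 transcripts, of which 33061 to 33846 had a base mean above 0 and 21391 to 23102 an adjusted p.

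Transcript identifiers were matched without their version to GENCODE 29, on the same build, which named 83066 of them and 92.9% to 93.1% of those above 0. Coordinates are those of GENCODE 29, counted from 1. Group levels were derived from the base mean and fold change, and a gene sum is the total of these levels over the transcripts of a gene, with a pseudocount of 1 in its log2 ratio. A level under 1 normalised count cannot be told from 0, so no fold is given for it. The sum carries no standard error. Where a text sentence names the authors' deposited table, its values were copied from it.

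A transcript was called at an adjusted p under 0.05. Named genes followed a rule fixed before the data were examined: the targets and their paralogs, the 6 largest rises and falls per comparison at a base mean of at least 100, up to 4 members of each list, and transcripts changed the same way in all 5. After the values were seen a further rule was added, since many of the largest changes were in genes whose sum changed little: the 6 largest rises and falls among main transcripts with a base mean of at least 100 whose gene sum moved the same way by at least 0.5 times as much. The genes introduced as largest rises and falls of each knockdown, and TPT1-AS1, SCARNA10 and SLMAP, came from that added rule. The 27 gene lists were fixed before the data were examined. Each used the transcript with the highest base mean per gene over the 5 tables, and was tested at 3 or more members with cameraPR of limma 3.58.1 on the deposited Wald statistics with a preset correlation of 0.01, Benjamini-Hochberg adjusted over 134 tests. No correlation could be estimated, since the tables hold no value per library, and 0.05 was tried as an alternative. The p-value of a list therefore sets its shift against the spread over genes and does not measure variation between cultures. A list's percentile came from 10000 random lists matched on base mean.

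The difference of 2 knockdowns was the difference of log2 fold changes over a standard error that subtracts the covariance of the shared controls, with a normal p and Benjamini-Hochberg adjustment. Correlations between comparisons were set beside groups simulated as unchanged against the same controls, with the real standard errors and seed 1. Calling of transcripts was tried on data simulated with 200 changed transcripts per log2 fold. The difference test was tried on simulated knockdowns with no true difference, and the list test on shuffled statistics. Alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, base mean minimums of 10 and 100, no filter, another null, centring, larger standard errors, ranks, random lists and independence. Further alternatives chosen after seeing the data were the gene sum, 1 transcript per gene, every transcript, transcripts with a group under 1 left out and another covariance. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used. Raw reads were not used here.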

Results

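RNA was measured in T-HESC, a line of human endometrial stromal fibroblasts immortalised with telomerase. Cells received siRNA against RXRA, RORB, HOXA4, PHB or MLLT11, or a control oligonucleotide, and RNA was collected after 48 hours. The 38 samples were 19 libraries sequenced in 2 runs each: 3 libraries per knockdown and 4 control cultures, of which each comparison used 3. Each knockdown had its own table of 100454 transcripts with no value per library. The depth of each sample was therefore unknown, and the mean normalised counts of a table summed to between 6.71e6 and 6.83e6. The authors' deposited tables called 662 transcripts changed after RXRA knockdown, 727 after RORB, 784 after HOXA4, 565 after PHB and 402 after MLLT11 knockdown, at an adjusted p under 0.05. For 386, 429, 514, 314 and 194 of these, in the same order, the gene summed over its transcripts moved the same way by at least 0.5 times as much on the log2 scale. In genes with a single detected transcript the sum is that transcript, so their calls met this rule almost by construction. With standard errors multiplied by the square root of 2, between 108 (MLLT11) and 202 (HOXA4) calls were left per comparison.

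Each targeted gene that could be measured fell in its own comparison. RXRA, a nuclear receptor that pairs with other receptors for vitamins and lipids, fell after its own knockdown from 208 to 32.9 normalised counts (log2 fold change -2.66 ± 0.31, adjusted p = 3.63e-15 in the authors' deposited table, transcript ENST00000481739.2, chromosome 9, 134326580 to 134437019). MLLT11, a small protein linked to leukaemia fusions, fell from 246 to 25.0 normalised counts after MLLT11 knockdown (-3.29 ± 0.30, adjusted p = 6.27e-24 in the authors' deposited table, ENST00000368921.5, chromosome 1, 151057758 to 151068497). PHB, a scaffold protein of the inner mitochondrial membrane, went from 715 to under 1 normalised count in its main transcript after PHB knockdown (adjusted p = 2.63e-19 in the authors' deposited table, ENST00000300408.7, chromosome 17, 49404052 to 49414880). Summed over its transcripts, PHB was at 5.40% of its control level. RORB, a nuclear receptor, and HOXA4, a homeobox transcription factor, were listed at 0 in their own comparisons, in 2 and 3 transcripts. This held for the controls too, so the 0 does not show silencing. RORB was at 0 in every other comparison as well, and HOXA4 in all but the PHB comparison (base mean 0.328). Their knockdown could therefore not be checked from RNA, and the libraries labelled RORB and HOXA4 rest on their labels. Of the 3 measurable targets in the other comparisons, only MLLT11 after HOXA4 knockdown passed the test, with a log2 fold change of 0.50 ± 0.13 and an adjusted p of 0.0105 in the authors' deposited table. RXRA had standard errors of 1.5 and 1.49 after RORB and HOXA4 knockdown in the authors' deposited table, against 0.24 after PHB and MLLT11 knockdown. The PHB main transcript had no p-value after RXRA knockdown, where the gene sum gave a log2 ratio of 0.16. Related family members did not pass the test in the comparison of their own relative, such as PHB2, the partner of PHB (-0.24 ± 0.13, adjusted p = 0.639 in the authors' deposited table), and RORA, a relative of RORB (0.96 ± 0.53, adjusted p = 0.559).

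**Figure D1:**
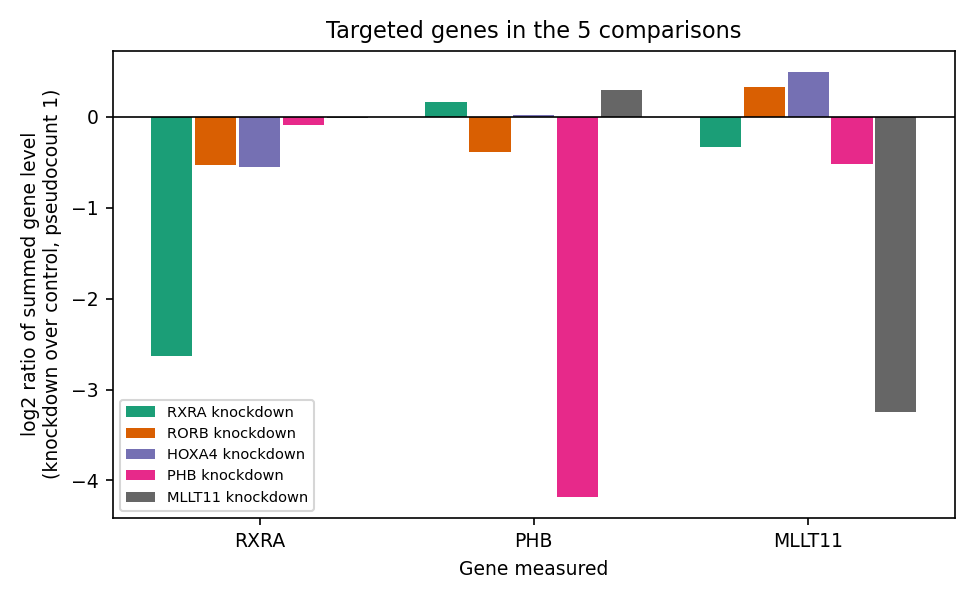
Bars show the log2 ratio of the summed gene level, knockdown over control with a pseudocount of 1, for RXRA, PHB and MLLT11 in each of the 5 comparisons, 1 value per comparison with no error bar because the tables hold no value per library. Each gene was lowest in its own comparison, at -2.63, -4.18 and -3.24, and the other bars lay between -0.55 and 0.49.

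After RXRA knockdown, the cell cycle and integrated stress response lists were shifted upward, the latter also after RORB, PHB and MLLT11 knockdown. PLXDC2, a transmembrane protein with a plexin-like domain, fell from 536 to 92.6 normalised counts (-2.53 ± 0.33 in the authors' deposited table), and B3GALT2, a galactosyltransferase, fell with a log2 fold change of -2.09 ± 0.37. PCDH10, a protocadherin (-1.84 ± 0.25), ATP6V0D1, a subunit of the vacuolar proton pump (-1.93 ± 0.50), and VTA1, a factor of endosomal sorting (-1.72 ± 0.49), were also lower in the authors' deposited table. PLAU, the urokinase plasminogen activator, rose by a log2 fold change of 3.30 ± 0.76, F2RL1, a receptor cleaved by proteases, by 1.92 ± 0.40, and IER3IP1, a protein of the secretory pathway, by 2.64 ± 0.30 in the authors' deposited table. SLMAP, a membrane protein of the striatin complex, went from under 1 to 298 normalised counts.

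Of 26 measured genes of the integrated stress response, 3 rose, none fell and 23 did not pass, with 5 rises when adjusted over the list alone. They were MTHFD2, a mitochondrial folate enzyme (0.95 ± 0.16), TRIB3, a pseudokinase (0.55 ± 0.14), and VLDLR, a lipoprotein receptor (2.35 ± 0.64), in the authors' deposited table. The list as a whole was shifted upward (median log2 fold change 0.29, limma adjusted p = 0.000565). The cell cycle list was also shifted upward (median 0.53, adjusted p = 5.37e-05), although 0 of its 33 members passed the DESeq2 test, also when adjusted over the list alone, and 7 rose and 1 fell at an unadjusted p under 0.05. Of 29 measured decidualization markers and regulators, 2 fell, 0 rose and 27 did not pass, with the same 2 when adjusted over the list alone. These were HOXA11, a homeobox factor of the uterus (-0.62 ± 0.15), and DKK1, an inhibitor of WNT signalling (-1.61 ± 0.44), in the authors' deposited table. That list's median was -0.44, or -0.28 with genes under 1 normalised count set to 1, and its adjusted p of 0.0102 became 0.122 with a preset correlation of 0.05 and 0.118 with every transcript. The 15 mitochondrially encoded genes had a median of 0.65 with 0 calls and 1 rise at an unadjusted p under 0.05 (adjusted p = 0.0102, and 0.0643 with a preset correlation of 0.05). Summed mitochondrial mRNA went from 0.110% to 0.121% of normalised counts, mitochondrial ribosomal RNA from 1.3% to 1.76% and the 5.8S and 45S-type RNAs from 1.45% to 1.86%. These 2 ribosomal shares varied between sets of controls, at 0.316% and 0.381% in the HOXA4 controls. The 18 circadian clock genes had a median of 0.40 with 0 calls, 4 rises at an unadjusted p under 0.05, 2 rises when adjusted over the list alone, and an adjusted p of 0.0425 that became 0.188 with a preset correlation of 0.05. The endothelial and pericyte list was lower (adjusted p = 0.0046) with 1 call among 10 members, KCNJ8, a potassium channel subunit that went from 164.1 to under 1 normalised count. This list's adjusted p was 0.253 by its percentile among random lists.

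Among partners and targets of the receptor, 1 of 28 steroid and nuclear receptors rose, VDR, the vitamin D receptor (0.77 ± 0.21), and 2 fell, RXRA itself and RARG, a retinoic acid receptor (-1.34 ± 0.37), in the authors' deposited table. The list did not pass (adjusted p = 0.502). Of 21 retinoid, LXR and PPAR target genes, ANGPTL4, a lipoprotein lipase inhibitor, rose from 1.19 to 20.1 normalised counts and FABP4, a fatty acid carrier, fell (-1.50 ± 0.45 in the authors' deposited table), and that list did not pass (adjusted p = 0.712). CSF1, a macrophage growth factor (-1.57 ± 0.36), and HLA-A, a class I antigen (-1.02 ± 0.23), were the 2 of 16 maternal-fetal signalling genes that fell in the authors' deposited table. ATP6V0D1, VTA1, PLAU, F2RL1, TRIB3, VLDLR, HOXA11, DKK1, VDR, RARG, ANGPTL4, FABP4, CSF1 and HLA-A did not pass with standard errors multiplied by the square root of 2. The 662 calls were 306 rises and 356 falls. In data simulated for this comparison, 19.0% of transcripts changed by a log2 fold of 1 and 38% of those changed by 2 were recovered.

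After RORB knockdown, the cell cycle list was shifted downward and the extracellular matrix list upward. The libraries labelled RORB had less CDC20, an activator of the anaphase-promoting complex (-3.11 ± 0.52), CDC6, which loads the replicative helicase (-1.90 ± 0.37), MCM4, a subunit of that helicase (-1.29 ± 0.14), and KIF20A, a mitotic kinesin (-1.51 ± 0.33), in the authors' deposited table. CDK2AP1, a binding partner of a cyclin-dependent kinase, fell from 1512 to 206 normalised counts (-2.88 ± 0.17, adjusted p = 1.02e-59 in the authors' deposited table, ENST00000261692.7, chromosome 12, 123260981 to 123272140). MSH2, a mismatch repair protein (-1.95 ± 0.26), and PBK, a mitotic kinase (-1.82 ± 0.54), were also lower in the authors' deposited table. Of 32 measured cell cycle genes, 12 fell, 0 rose and 20 did not pass, with 18 falls when adjusted over the list alone. The list had a median log2 fold change of -1.36 (limma adjusted p = 1.01e-27).

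MPZL1, a receptor of the immunoglobulin family, rose from 426 to 2191 normalised counts (2.36 ± 0.11, adjusted p = 4.17e-92 in the authors' deposited table, ENST00000359523.7, chromosome 1, 167721950 to 167791919). KCNH1, a potassium channel (2.80 ± 0.62), TNFSF18, a cytokine of the TNF family (2.82 ± 0.43), and ACTC1, the cardiac muscle actin (3.18 ± 0.89), also rose in the authors' deposited table. SLMAP went from under 1 to 338 normalised counts, against the same control libraries as for RXRA knockdown. The readthrough transcript ANKHD1-EIF4EBP3, which shares sequence with ANKHD1 and is uncertain for that reason, had a log2 fold change of 6.25 ± 1.46 in the authors' deposited table. SCARNA10, a small RNA of Cajal bodies with 1 transcript, went from 399 to under 1 normalised count.

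Among 31 extracellular matrix genes, SPARC, a collagen-binding glycoprotein, rose (0.76 ± 0.08, adjusted p = 2.48e-19 in the authors' deposited table), 0 fell and 30 did not pass, with 4 rises when adjusted over the list alone. The list was shifted upward (median 0.27, limma adjusted p = 0.0013). The 13 mitochondrially encoded genes measured had a median of 0.84 (adjusted p = 0.000153) with 0 members past the test and 2 rises at an unadjusted p under 0.05. That list was also higher after RXRA knockdown, against the same control libraries, and did not differ between these knockdowns (limma adjusted p = 0.765). A part of its rise from the level of those controls therefore stays open. The 44 nuclear respiratory chain genes had a median of -0.25 with 0 calls and 3 falls at an unadjusted p under 0.05 (adjusted p = 0.00136, and 0.0679 with a preset correlation of 0.05). Of 27 integrated stress response genes, TRIB3 rose (0.69 ± 0.14 in the authors' deposited table) and 0 fell, and the list was shifted upward (median 0.46, limma adjusted p = 0.000491, and 0.231 when every transcript was used). Of 23 TGF-beta and contractile genes, INHBA, a subunit of activin, rose (1.12 ± 0.30 in the authors' deposited table), with a list adjusted p of 0.0446 that became 0.226 with a preset correlation of 0.05. The endothelial and pericyte list was lower (adjusted p = 0.0133, and 0.237 by ranks), with KCNJ8, from 164.4 to under 1 normalised count, as the 1 call among 9 members. The control level of KCNJ8 came from the same libraries as for RXRA knockdown. Among the members of other lists that rose were WNT5A, a WNT ligand of the stroma (0.75 ± 0.18), and ESR1, the oestrogen receptor (2.87 ± 0.73, from 2.12 to 15.5 normalised counts), in the authors' deposited table. The calls of KIF20A, PBK, KCNH1, ACTC1, ANKHD1-EIF4EBP3, INHBA, WNT5A and ESR1 did not pass with standard errors multiplied by the square root of 2. The 727 calls were 346 rises and 381 falls. Simulated changes of a log2 fold of 1 and of 2 were recovered in 13.5% and 38% of transcripts for this comparison.

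After HOXA4 knockdown, the cholesterol synthesis list was shifted upward. The libraries labelled HOXA4 had more ACAT2, which condenses acetyl-CoA (0.45 ± 0.08), EBP, a sterol isomerase (0.54 ± 0.13), MVD, a mevalonate pathway decarboxylase (0.55 ± 0.14), and MSMO1, a sterol oxidase (0.39 ± 0.12), in the authors' deposited table. These were the 4 rises among 23 measured cholesterol synthesis genes, 0 fell and 19 did not pass, with 9 rises when adjusted over the list alone. The list had a median log2 fold change of 0.45 (limma adjusted p = 1.95e-09). PODXL, a sialomucin of the cell surface, rose from 32.4 to 221 normalised counts (2.77 ± 0.28, adjusted p = 1.28e-19 in the authors' deposited table, ENST00000378555.8, chromosome 7, 131504131 to 131556607), and F2RL1 rose by 2.07 ± 0.30.

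COL7A1, the collagen of anchoring fibrils (1.55 ± 0.28), USP37, a deubiquitinase (1.39 ± 0.22), PGM2L1, a sugar-phosphate enzyme (1.36 ± 0.22), and PRR5L, which binds an mTOR complex (1.33 ± 0.36), also rose in the authors' deposited table. RGCC, a regulator of the cell cycle (-2.79 ± 0.58), WIPF1, an actin regulator (-1.98 ± 0.29), ATP6V0E1, a subunit of the vacuolar proton pump (-1.98 ± 0.27), and TPGS2, a subunit of a tubulin-modifying enzyme (-1.91 ± 0.28), fell in the authors' deposited table. The fall of the readthrough HNRNPUL2-BSCL2 (-2.52 ± 0.32 in the authors' deposited table) is uncertain because it shares sequence with HNRNPUL2 and BSCL2. Of 30 decidualization markers and regulators, 4 fell, 0 rose and 26 did not pass, with 6 falls when adjusted over the list alone. They were BMP2, a growth factor of decidualization (-1.94 ± 0.49), its receptor BMPR2 (-0.37 ± 0.10), DKK1 (-1.14 ± 0.23) and HOXA11 (-0.44 ± 0.12), in the authors' deposited table. The list itself had a median of -0.24 and did not pass (limma adjusted p = 0.0572).

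Of 23 TGF-beta and contractile genes, 3 rose and 1 fell, and 19 did not pass. TGFB2, a ligand of the pathway, rose from 12.95 to 128 normalised counts (3.30 ± 0.62), with SERPINE1, a plasminogen activator inhibitor (0.72 ± 0.20), and CTGF, a matricellular protein (0.62 ± 0.19), while CALD1, an actin-binding protein, fell (-0.80 ± 0.17), in the authors' deposited table. Adjusted over the list alone, 4 rose and 2 fell, and the list's adjusted p of 0.0237 became 0.162 with a preset correlation of 0.05. The cell cycle list was higher (median 0.24, adjusted p = 0.00726, and 0.115 with a preset correlation of 0.05), with CDC6 (0.76 ± 0.17) and MCM2, a subunit of the replicative helicase (0.66 ± 0.20), as the 2 calls among 33 members in the authors' deposited table. Of 68 ribosomal protein genes, 4 fell and 1 rose, with a list median of -0.13 (adjusted p = 0.000153, and 0.247 when every transcript was used). The called RPL14 transcript rose (0.71 ± 0.16 in the authors' deposited table) while the summed RPL14 level gave a log2 ratio of -0.01. Among 26 interferon-stimulated genes 3 fell and 0 rose. IFIT3 and IFIT2, antiviral proteins that bind RNA, had main transcripts that went to under 1 normalised count and gene sums with log2 ratios of -0.70 and -1.21, and IFIT5 fell (-0.62 ± 0.15 in the authors' deposited table). The interferon list passed as lower (adjusted p = 0.0309) with a median of 0.00, and its adjusted p was 0.199 with a preset correlation of 0.05. DCN, a small proteoglycan (-1.45 ± 0.33), LUM, a related proteoglycan (-0.74 ± 0.13), and THBS1, a matrix glycoprotein (-0.57 ± 0.17), were the 3 of 31 extracellular matrix genes that fell, and 0 rose, in the authors' deposited table. ATP5F1C, a subunit of ATP synthase, was the 1 call among 44 nuclear respiratory chain genes (-1.19 ± 0.17 in the authors' deposited table). EBP, MVD, MSMO1, PRR5L, RGCC, BMP2, BMPR2, DKK1, HOXA11, SERPINE1, CTGF, CALD1, CDC6, MCM2, RPL14, IFIT5, DCN, THBS1 and MLLT11 did not pass with standard errors multiplied by the square root of 2. The 784 calls were 358 rises and 426 falls. For this comparison, 21.0% and 37% of simulated changes of a log2 fold of 1 and 2 were recovered.

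After PHB knockdown, the p53 target list was shifted upward and the cell cycle list downward. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 2126 to 3385 normalised counts (0.67 ± 0.11, adjusted p = 8.76e-07 in the authors' deposited table, ENST00000244741.9, chromosome 6, 36678658 to 36687339). SESN1, a stress-induced sestrin (1.07 ± 0.23), BBC3, a promoter of apoptosis (0.84 ± 0.20), and TIGAR, a regulator of glycolysis (0.61 ± 0.14), rose in the authors' deposited table. Of 23 measured p53 target genes, 8 rose, 0 fell and 15 did not pass, with 12 rises when adjusted over the list alone. The list had a median log2 fold change of 0.59 (limma adjusted p = 2.3e-15).

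Of 33 cell cycle genes, 2 fell, 0 rose and 31 did not pass, with 3 falls when adjusted over the list alone. CDC6 (-1.57 ± 0.33) and MCM2 (-1.02 ± 0.23) were those calls in the authors' deposited table, and the list had a median of -0.28 (limma adjusted p = 4.85e-05). Among 27 integrated stress response genes 3 rose and 1 fell, with 7 rises and 1 fall when adjusted over the list alone. TRIB3 (0.89 ± 0.14) and the serine synthesis enzymes PHGDH (0.65 ± 0.20) and PSAT1 (0.41 ± 0.09) rose, and SLC7A11, a cystine transporter, fell (-1.33 ± 0.16), in the authors' deposited table. That list's median was 0.34 (adjusted p = 0.000779, and 0.0752 when every transcript was used). Of 24 cholesterol synthesis genes, 4 fell and 0 rose, with the same 4 when adjusted over the list alone. MVD (-0.46 ± 0.12) and DHCR24, a sterol reductase (-0.49 ± 0.14), were lower in the authors' deposited table, while the MVK and LSS transcripts that fell belonged to genes whose sums had log2 ratios of -0.66 and -0.18. The cholesterol list had a median of -0.16 (adjusted p = 0.00252, and 0.0937 by ranks, 0.0752 with every transcript and 0.133 by its percentile among random lists). The mitochondrial quality control list, which holds PHB2, had 0 calls among 21 members and 1 rise at an unadjusted p under 0.05, and its median was -0.02 (adjusted p = 0.831).

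Among main transcripts with a base mean of at least 100, the largest rises whose gene sum also moved were UCHL3, a ubiquitin hydrolase (2.06 ± 0.39), LAMA4, a laminin chain (1.95 ± 0.30), MAMDC2, a secreted proteoglycan (1.45 ± 0.21), ALDH2, the mitochondrial aldehyde dehydrogenase (1.36 ± 0.24), MRPS18C, a mitochondrial ribosomal protein (1.36 ± 0.37), and MIGA1, a mitochondrial fusion factor (1.19 ± 0.24), in the authors' deposited table. EIF2D, a translation initiation factor (-3.83 ± 0.88), C5orf24 (-3.32 ± 0.16), SLC17A5, a lysosomal sialic acid transporter (-2.41 ± 0.32), SV2A, a vesicle glycoprotein (-2.08 ± 0.38), CALU, a calcium-binding protein of the secretory pathway (-1.90 ± 0.39), and RGCC (-1.89 ± 0.22) fell in the authors' deposited table. Of 31 extracellular matrix genes 2 rose and 2 fell, among them LUM (-0.97 ± 0.18) and COL5A2, a fibrillar collagen chain (-1.22 ± 0.32), as falls in the authors' deposited table. CXCL8, a neutrophil chemokine, was the 1 call among 17 inflammatory genes (-1.94 ± 0.45 in the authors' deposited table). SESN1, BBC3, TIGAR, CDC6, MCM2, PHGDH, PSAT1, MVD, DHCR24, LSS, MRPS18C, MIGA1, EIF2D, CALU, COL5A2 and CXCL8 did not pass with standard errors multiplied by the square root of 2. The 565 calls were 231 rises and 334 falls. Simulated log2 changes of 1 and 2 were recovered in 19.0% and 39% of transcripts for this comparison.

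After MLLT11 knockdown, the cell cycle list was shifted downward and the p53 target and ribosomal protein lists upward. TOP2A, the topoisomerase of dividing cells (-0.75 ± 0.14), KIF20A (-0.89 ± 0.18), CENPF, a kinetochore protein (-0.70 ± 0.16), and CCNB1, a mitotic cyclin (-0.75 ± 0.17), fell in the authors' deposited table. MKI67, a marker of proliferation, went from 632 to 265 normalised counts (-1.25 ± 0.36 in the authors' deposited table), and SPAG5 (-1.29 ± 0.26) and TPX2 (-1.18 ± 0.28), both spindle proteins, were also lower. Of 33 cell cycle genes 8 fell, 0 rose and 25 did not pass, with 12 falls when adjusted over the list alone. The list had a median log2 fold change of -0.73 (limma adjusted p = 4.63e-18).

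Of 22 p53 target genes 5 rose, 0 fell and 17 did not pass, with 10 rises when adjusted over the list alone. CDKN1A (0.64 ± 0.11), MDM2, the ligase that degrades p53 (0.51 ± 0.12), FDXR, a mitochondrial reductase (1.5 ± 0.38), and BBC3 (0.74 ± 0.19) were among them in the authors' deposited table, and the list had a median of 0.43 (limma adjusted p = 5.28e-13). Of 65 ribosomal protein genes 3 rose, 1 fell and 61 did not pass, with a list median of 0.32 (limma adjusted p = 2.13e-14) and 4 rises and 1 fall when adjusted over the list alone. RPL32 (0.69 ± 0.14), RPL35A (0.89 ± 0.22) and RPL14 (1.00 ± 0.28) rose in the authors' deposited table, with gene sums at log2 ratios of 0.36, 0.42 and 0.36. The 28 integrated stress response genes had a median of 0.42 with 0 calls, 8 rises at an unadjusted p under 0.05, 2 rises when adjusted over the list alone, and an adjusted p of 4.2e-05 that became 0.138 when every transcript was used. Among 22 TGF-beta and contractile genes 2 fell and 0 rose, ACTG2 (-1.90 ± 0.33) and ACTA2 (-0.70 ± 0.21), both smooth muscle actins, in the authors' deposited table. The adjusted p of this list was 0.0278, and 0.169 with a preset correlation of 0.05. The 45 nuclear respiratory chain genes had a median of 0.12 with 0 calls and 1 rise at an unadjusted p under 0.05 (adjusted p = 0.0228, and 0.243 with a preset correlation of 0.05). Among 12 abundant non-coding RNAs 1 transcript rose, of RMRP, the RNA of a mitochondrial RNA processing enzyme, and the list had an adjusted p of 0.00726 that became 0.744 when every transcript was used. Another RMRP transcript went from 24747 to 8.95 normalised counts, and the summed RMRP level had a log2 ratio of 0.23.

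VCAN, a large matrix proteoglycan, fell from 1221 to 419 normalised counts (-1.54 ± 0.22 in the authors' deposited table, ENST00000343200.9, chromosome 5, 83471674 to 83582303), and STRADB, a pseudokinase, fell (-1.18 ± 0.26). UCHL3, which went from 52.7 to 227 normalised counts, SLC16A14, a transporter of the monocarboxylate family (2.01 ± 0.25), FST, an inhibitor of activin (1.69 ± 0.24), and TXNIP, an inhibitor of thioredoxin (1.64 ± 0.26), rose in the authors' deposited table. UCHL3 also rose after PHB knockdown, which used the same control libraries. TPT1-AS1, antisense to TPT1, went from under 1 to 995 normalised counts. A readthrough transcript of NME1-NME2 went from under 1 to 627 and is uncertain because it shares sequence with NME1 and NME2. KIF20A, CENPF, CCNB1, MKI67, SPAG5, TPX2, MDM2, FDXR, BBC3, RPL32, RPL35A, RPL14, ACTA2, RMRP and STRADB did not pass with standard errors multiplied by the square root of 2. The 402 calls were 196 rises and 206 falls. For this comparison, 21.0% of simulated log2 changes of 1 and 36.5% of those of 2 were recovered.

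The direct tests of differences between knockdowns numbered 266, each of a list in a pair of knockdowns, and 50 passed with limma. The cell cycle list differed between RXRA and RORB knockdown (adjusted p = 6.76e-34), which shared all 3 controls, between RORB and HOXA4 knockdown (1.01e-25) and between PHB and MLLT11 knockdown (0.0027), and not between RXRA and HOXA4 knockdown (0.159). The p53 target list differed between RORB and PHB knockdown (8.05e-06) and between RXRA and PHB knockdown (0.00288), and did not pass between PHB and MLLT11 knockdown (0.644). PHB and MLLT11 knockdown, the only ones after which that list passed, shared all 3 controls. A part of its rise from the level of those controls therefore stays open. The cholesterol list differed between HOXA4 and PHB knockdown (9.28e-09) and between RXRA and HOXA4 knockdown (0.000124), and the ribosomal list between HOXA4 and MLLT11 knockdown (3.83e-17). The integrated stress response list, higher after the other knockdowns, had a median of 0.19 after HOXA4 knockdown (limma adjusted p = 0.164). It differed in no pair, with a lowest adjusted p of 0.158 between RORB and HOXA4 knockdown. By the labels' descriptions, the comparisons in which this list passed all used control culture 3, and the HOXA4 comparison did not. A part of its rise from the level of that culture therefore stays open. In all, 31 of 134 list tests passed, 18 upward and 13 downward, and 11 of them passed under every alternative tried. Lists that lost their call under at least 3 of the 5 alternatives were circadian clock genes after RXRA, endothelial and pericyte markers after RXRA and RORB, and TGF-beta and contractile genes after RORB, HOXA4 and MLLT11 knockdown. The same held for interferon-stimulated genes after HOXA4, cholesterol synthesis after PHB, nuclear respiratory chain genes and abundant non-coding RNAs after MLLT11, and the targets' own list after PHB and MLLT11 knockdown. Lists that passed the limma test after no knockdown had these lowest adjusted p-values: inflammatory genes 0.0932, mitochondrial quality control 0.164, nuclear receptors 0.197, maternal-fetal signalling 0.23 and retinoid, LXR and PPAR targets 0.231. The remaining lists without a call were stromal identity at 0.259, epithelial markers at 0.331, paralogs of the targets at 0.339, hypoxia and glycolysis at 0.352, HOX genes at 0.39, immune markers at 0.617 and the unfolded protein response at 0.651. After RXRA knockdown the inflammatory list had a median of 0.59 (limma adjusted p = 0.197, and 0.00631 by its percentile among random lists). It differed between RXRA and PHB knockdown (limma adjusted p = 0.0142), and epithelial markers differed between RXRA and HOXA4 knockdown (0.00818). The list of the 5 targets, counted among the 31, passed after PHB (6.34e-06, and 0.28 by ranks and 0.481 by percentile) and MLLT11 knockdown (1.72e-05, and 0.984 by ranks and 0.979 by percentile). Its only call at an adjusted p under 0.05 there was the silenced gene itself.

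**Figure D2:**
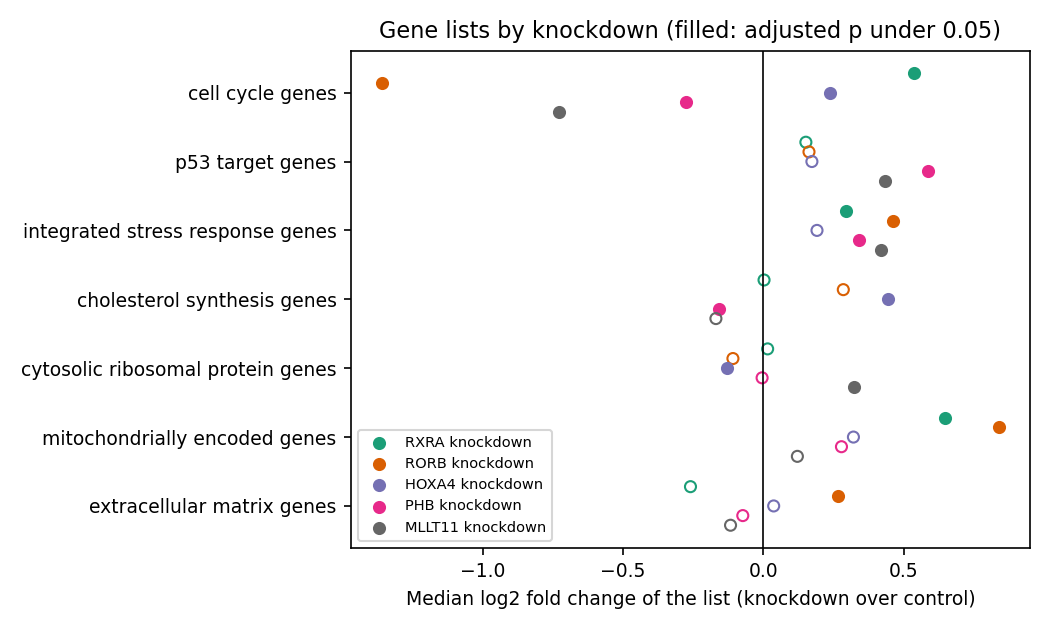
Points show the median log2 fold change of 7 gene lists, knockdown over control, in each of the 5 comparisons, filled where the limma adjusted p was under 0.05. The cell cycle list lay at -1.36 after RORB and -0.73 after MLLT11 knockdown, and at 0.53 after RXRA knockdown.

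Some calls were of transcripts near 0 in 1 group whose gene sum changed little. Of the 3140 calls, 506 had a group under 1 normalised count and the other at 20 or more. Of the 453 of these in genes with several detected transcripts, 73.3% had a summed gene level within a factor of 1.5 and 92.1% had another transcript that moved the opposite way. After RXRA knockdown, MGAT5, a glycosyltransferase of N-glycan branching, had 1 transcript that went from 1603 to under 1 normalised count and another that went from under 1 to 1455, with a gene sum at a log2 ratio of -0.14. PPP3CA, the catalytic subunit of calcineurin, went from 791 to under 1 in 1 transcript and had a gene sum at 0.02, and REST, a repressor of neuronal genes, went from under 1 to 791 with a gene sum at 0.04. After RORB knockdown, GFPT1, an enzyme of hexosamine synthesis (gene sum 0.12), LNPK, an endoplasmic reticulum protein (-0.10), and PLK2, a polo-like kinase (0.09), each had 1 transcript that went to under 1 and another that rose from under 1, and PAICS, a purine synthesis enzyme, lost its main transcript with a gene sum at -1.27. HOXA4 knockdown libraries showed calls with a group under 1 for AR, the androgen receptor (gene sum -0.18), TEAD1, a transcription factor of the Hippo pathway (-0.07), and C1S, a complement protease (-0.06). RPL34, a ribosomal protein with near-identical copies and so uncertain, went from 1351 to under 1 in its main transcript, with a gene sum at -0.39. After PHB knockdown, NBR1, an autophagy receptor (gene sum -0.15), ATP2C1, a Golgi calcium pump (0.31), and USP16, a histone deubiquitinase (0.27), had such calls. After MLLT11 knockdown, STAT6, a transcription factor of interleukin signalling (gene sum 0.24), and PFKP, a phosphofructokinase (-0.33), each had a transcript lost and another gained, and UBE2C, a ubiquitin-conjugating enzyme of mitosis, lost its main transcript with a gene sum at -1.47.

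**Figure D3:**
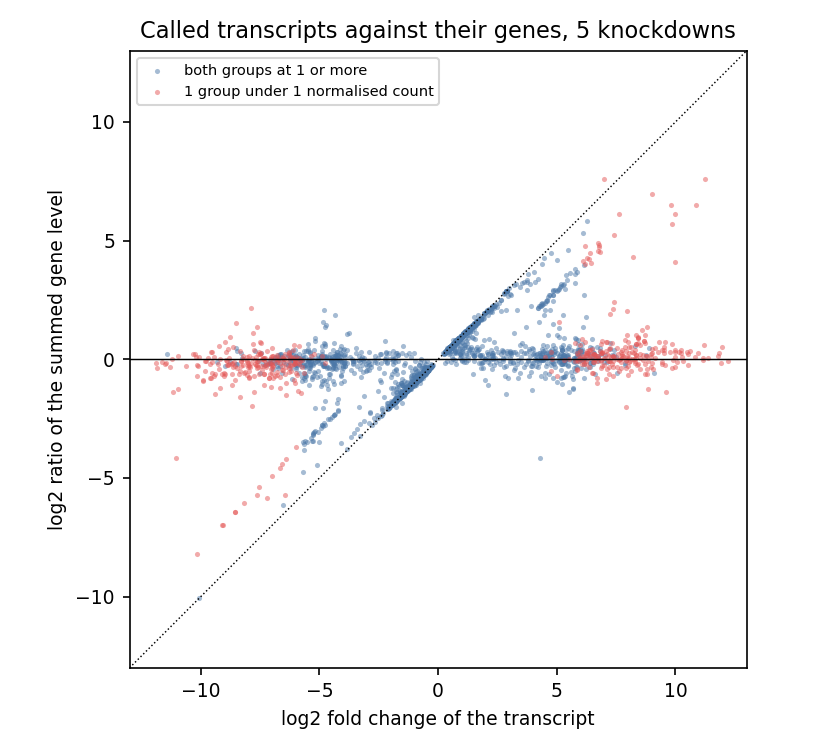
Each point is a called transcript of the 5 comparisons with a gene symbol, the horizontal axis its log2 fold change and the vertical axis the log2 ratio of its summed gene level, with a dotted line of equality. Calls with 1 group under 1 normalised count lie at the far left and right, and 73.3% of those in genes with several transcripts had a sum within a factor of 1.5.

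Few transcripts changed in all comparisons. FZD6, a receptor for WNT ligands, rose in all 5, with log2 fold changes of 1.15 ± 0.18 after RXRA, 0.94 ± 0.17 after RORB, 1.12 ± 0.12 after HOXA4, 0.67 ± 0.19 after PHB and 0.84 ± 0.17 after MLLT11 knockdown in the authors' deposited tables (ENST00000358755.5, chromosome 8, 103298831 to 103332859). A transcript of FGF7, a fibroblast growth factor for epithelium, also rose in all 5, while the summed FGF7 level had log2 ratios between -0.79 and 0.54. All 5 comparisons shared control culture 1. With standard errors multiplied by the square root of 2, FZD6 did not pass after PHB and MLLT11 knockdown, nor the FGF7 transcript after any. Over the 10 pairs of comparisons, 634 calls were shared in the same direction and 123 in opposite directions. Unchanged groups simulated against the same controls shared 522 between lists of the same lengths, and independent lists would share 80.3. The simulated lists took the largest statistics of noise alone, without requiring an adjusted p under 0.05. The 522 therefore do not give the part of the 634 that came from shared controls. Nothing else common to the comparisons was simulated. Controls could not be split, so part of the excess over independent lists may come from the shared controls. Across transcripts, which are not independent replicates, log2 fold changes correlated with r between 0.345 and 0.391 for pairs with 2 shared controls (simulated 0.301 to 0.321) and of 0.513 and 0.560 for pairs with 3 (simulated 0.484 and 0.496). Covariances were 0.522 to 0.644 with 2 shared controls (simulated 0.369 to 0.405) and 0.855 and 0.884 with 3 (simulated 0.633 and 0.621). At a base mean of at least 100, covariances were 0.152 to 0.214 with 2 shared controls (simulated 0.145 to 0.171) and 0.244 and 0.288 with 3 (simulated 0.255 and 0.268). The test of the difference itself called 6138 transcripts over the 10 pairs, from 390 between RXRA and HOXA4 knockdown to 1109 between RXRA and RORB knockdown, and 2270 with the fold changes treated as independent.

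**Figure D4:**
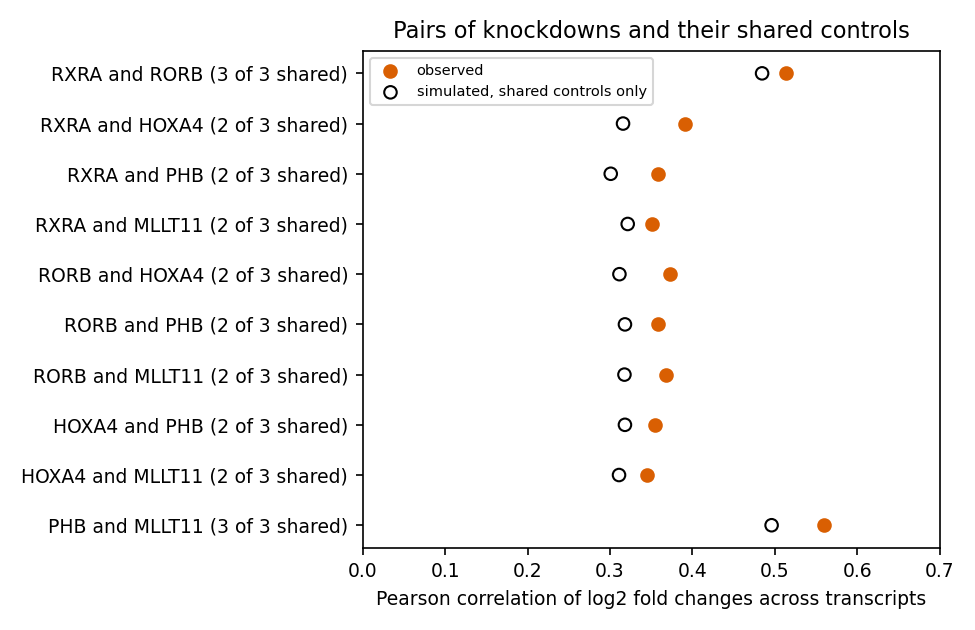
Filled points show the observed Pearson correlation of log2 fold changes across transcripts for each of the 10 pairs of knockdowns, and open points that of unchanged groups simulated against the same shared controls. Observed values over all tested transcripts lay above simulated ones in every pair, by a median of 0.0451, but at a base mean of at least 100 they lay below in 7 of the 10 pairs.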

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

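The alternatives that sum genes, keep 1 transcript per gene, use every transcript, leave out transcripts with a group under 1 normalised count or take the covariance from the smaller standard error were chosen after the result was seen. In order of RXRA, RORB, HOXA4, PHB and MLLT11 knockdown, an adjusted p under 0.01 left 426, 458, 485, 373 and 260 calls, by its construction. Standard errors multiplied by the square root of 2 left 179 calls for RXRA, 191 for RORB, 202 for HOXA4 and 108 for MLLT11, and for PHB 68 rises and 97 falls (about 1.7e2 calls), again by construction. An absolute log2 fold change of at least 1 left 434 calls for HOXA4 and 357 for PHB knockdown. Calls whose gene sum moved the same way numbered 386, 429, 514, 314 and 194, including those in genes with a single detected transcript, where the sum is that transcript. With 1 transcript per gene, calls were 408 for RXRA, 353 for PHB and 222 for MLLT11 knockdown, since fewer transcripts were counted. The other alternatives run on these counts stayed within 1.5 times.

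The 31 list calls became 20 with a preset correlation of 0.05, by construction, and 14 with every transcript, for which the cause was not tested. The lower interferon list after HOXA4 knockdown showed no shift by its percentile among random lists (50.2, unadjusted p = 0.995), nor by ranks (adjusted p = 0.798). Its 3 calls, IFIT3, IFIT2 and IFIT5, had Wald statistics of -8.97, -8.18 and -4.19 in the authors' deposited table, against a list mean of -0.777. The list without them was not tested. Shared calls fell from 634 to 325 at an adjusted p under 0.01, 409 at a base mean of at least 100 and 384 with the gene sum. Difference calls went from 6138 to 2270 with fold changes treated as independent and 1161 with the larger standard errors, both by construction. Of the named transcripts, 125 lost their call with the larger standard errors, 21 with an empirical null, 18 with adjustment over every p-value and 4 with centring.

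No paired analysis was possible because the tables hold no value per library. For the same reason leaving out each replicate, a replicate block, other count tools, another normalization of counts and other splits of the libraries were not run. With 3 libraries against 3, the 10 splits could not give a share under 0.05. Small changes could be missed: for MLLT11 knockdown, 1.0% of transcripts simulated with a log2 change of 0.5 were recovered.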

Other observations

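The tests of explanations below were chosen after the result was seen, except those of widely varying transcripts. MMP1, DKK1, PDGFRA and IFIT1 come from different lists and were singled out after their values were seen, because their calls had different directions between knockdowns. MMP1, an interstitial collagenase, rose after RXRA knockdown (1.12 ± 0.32) and fell after RORB (-1.58 ± 0.47) and HOXA4 knockdown (-0.96 ± 0.16) in the authors' deposited tables. DKK1 fell after RXRA and HOXA4 knockdown and rose after MLLT11 knockdown (0.74 ± 0.22 in the authors' deposited table). PDGFRA, a growth factor receptor of fibroblasts, rose after RXRA (0.30 ± 0.05), RORB (0.51 ± 0.12) and MLLT11 knockdown (0.40 ± 0.07) and fell after HOXA4 knockdown (-0.23 ± 0.06) in the authors' deposited tables. IFIT1, an antiviral protein, fell after RXRA (-1.25 ± 0.22) and PHB knockdown (-0.70 ± 0.17) and rose after MLLT11 knockdown (0.61 ± 0.13) in the authors' deposited tables. With standard errors multiplied by the square root of 2, MMP1 did not pass after RXRA and RORB knockdown, nor DKK1 in its 3 comparisons, PDGFRA after RORB and HOXA4 knockdown and IFIT1 after PHB and MLLT11 knockdown.

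Mitochondrial ribosomal RNA made up 1.19% of normalised counts in controls and 0.320% after PHB knockdown. It was at 1.3% in controls and 1.76% after RXRA knockdown, at 1.28% and 1.25% for RORB and at 1.22% in both groups for MLLT11. In the HOXA4 comparison, the only one without control culture 3 by the labels' descriptions, it was 0.316% in controls and 0.318% after knockdown. The 5.8S and 45S-type RNAs went from 1.34% to 0.379% in the PHB comparison, from 1.45% to 1.86% for RXRA, from 1.42% to 1.23% for RORB, from 1.36% to 1.20% for MLLT11 and from 0.381% to 0.509% for HOXA4. In both classes the HOXA4 controls, without culture 3, lay close to PHB knockdown (0.316% and 0.381% against 0.320% and 0.379%). The lower shares after PHB knockdown may therefore rest on that control culture. RNA5-8SN2, among near-identical copies and so uncertain, had a log2 fold change of 2.85 ± 0.89 after RXRA knockdown in the authors' deposited table, and did not pass with standard errors multiplied by the square root of 2.

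Transcripts that were called with a group under 1 normalised count may reflect reads assigned to 1 or another transcript of a gene rather than a change of the gene. Of such calls in genes with several transcripts, 73.3% kept a gene sum within a factor of 1.5. Widely varying transcripts were 20.6 times as frequent in genes with several transcripts as in genes with 1, and there were 106 of them per such call with a base mean of at least 100, more than chance separation of the libraries needs. A regulated switch of isoforms stays open and was not tested, as the tables hold no value per library.

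The correlation between knockdowns may come in part from shared controls: it exceeded the simulated one by a median of 0.0451 over the 10 pairs, and at a base mean of at least 100 it lay below in 7 of them. Covariances, which real changes in a single comparison do not lower, exceeded the simulated ones in all 10 pairs, and in 6 at a base mean of at least 100. Shared calls were 634 against 522 simulated, but the simulated lists were filled without the adjusted p threshold, so these counts cannot decide. A response common to the targeting siRNAs, or one to the control siRNA, remains open.

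The level of the shared controls alone did not account for the lower cell cycle list after RORB and MLLT11 knockdown. In pairs with the same controls, the list differed between RORB and RXRA knockdown (limma adjusted p = 6.76e-34) and between MLLT11 and PHB knockdown (0.0027). After RXRA knockdown its median was 0.53, opposite to RORB knockdown. After PHB knockdown it was also lower (median -0.28), so a part from the control level stays open for MLLT11 knockdown. Reads moved between transcripts were argued against, as the summed gene levels had medians of -1.3 and -0.71. A consequence of the knockdown and an effect of the siRNA on other RNAs both remain open as possible explanations. Each target had no second siRNA to compare, and RORB itself was listed at 0 in every comparison, controls included. A difference between the cultures of the groups also remains open, as no value per library was available.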
